A study of Mus musculus with 76 samples.

How the data were processed

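The samples were 76 RNA libraries of 1000 sorted mouse cells each, made by low-input cDNA amplification and tagmentation. They cover 15 natural and 9 induced groups of 2 to 4 libraries, and groups were taken from the labels. The authors demultiplexed the reads with bcl2fastq and used TopHat, Cufflinks 2.2.1 and Cuffnorm with the mouse build NCBIM37, and the deposited values are FPKM, with 1 row per Ensembl gene and 1 column per library. The processing notes give no parameters, no annotation version and no library normalization method of Cuffnorm. The table holds 37980 genes. Symbols came from the GENCODE vM21 annotation of GRCm38, which is not the build the authors used, and 32916 IDs (86.7%) had one.

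Each value was checked for its scale and for copies. The totals of FPKM per library ran from 667700 to 2004000. Replicates 1 and 3 of the pro/pre-B group were identical, so replicate 3 was left out and that group held 3 libraries. Read counts were not used here. The depth was placed from 4285 genes with a single transcript of at least 1000 bases, whose low values are near multiples of 1 fragment. The low values within 0.2 of a whole number of fragments made up 74.6% to 94.0% of them. A gene listed at 0 in a library was therefore below about 1 fragment there, and a fold change against a group listed at 0 was not given.

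Values were transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 2 libraries were kept, which left 17416, of which 16304 had a symbol. A single model with 1 mean per group was fitted to all libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings, 51 residual degrees of freedom). The test was two-sided, p was adjusted by the Benjamini-Hochberg method over genes within a comparison, and the threshold was an adjusted p of 0.05. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fit was also tested on simulated data made from these libraries. With the group sizes of the DP comparison, 53% of 2-fold and 95% of 4-fold changes were found and 9.2% of calls were false. With those of DN3 the values were 23%, 76% and 8.33%. Both false shares lay above the threshold of 0.05, so calls can be less strict than that threshold says. The simulated noise was drawn separately for each gene and library, without batch effects or correlation between genes.

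There were 19 comparisons: induced against natural cells at 9 stages and on average, induced BM ETP, natural BM ETP and HSC against pro/pre-B cells, the step from DN3 to DP and the difference of CD4 SP and CD8 SP in each source, and the difference of each of these between sources. Pearson correlation across genes placed each induced library among the 15 natural groups. Gene lists were tested with camera of limma (preset correlation 0.01, and an estimated correlation beside it), adjusted over the lists of a comparison, and members were counted over all genes and adjusted over the list alone. The 21 lists tested were B lineage, immunoglobulin constant, T lineage, stem and progenitor, beta selection, DP stage, T cell receptor signaling, single positive maturation, CD4 lineage, CD8 lineage and cytotoxic, natural killer and innate, myeloid, dendritic, erythroid, thymic stroma, proliferation, interferon, p53 response, immediate early and stress, Hox, and mitochondrially encoded genes. Sex-linked genes were given as values. Of 399 tests of a list in a comparison, 158 passed, and 106 passed with an estimated correlation.

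The lists, comparisons, tests, named-gene rule and alternatives other than those named below as later were set before the data were examined. The rule admits Hoxb5, any member of a list that is described, and per comparison the 8 highest and 8 lowest fold changes among genes past the threshold with a mean of at least 5 FPKM in the higher group and libraries that do not overlap. Predicted genes, pseudogenes, small RNAs and receptor segments were left out of that last part. The rule admits more genes than the text gives. Which of them were given as examples, and which lists were described, was decided after their values were seen. Some examples whose calls were lost under alternatives had been exchanged for others once those alternatives were known, and the earlier examples were then restored, with the adjusted p of their lost calls, singly or as a range. The counts of lost calls cover every gene the rule admits for the lists described, not the examples alone. Ddx3y, Xist, Rps3a2 and Rps27rt were named after their values were seen.

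Alternatives changed 1 choice at a time: a pseudocount of 0.1, no filter on low values, each library scaled to an equal total, quantile normalization, library weights, a block term for libraries of the same number, only the groups of a comparison in the fit, and each library of the groups left out in turn. For correlations, Spearman's coefficient and the genes of highest variance were tried, and for lists the estimated correlation. Chosen after seeing the data were fits without the myeloid group, with protein-coding genes other than ribosomal protein and mitochondrial genes, and without natural DN1 libraries 1 and 2 and natural DN2 library 2. Labels do not say that a replicate number marks a shared animal, day or batch, and they give no batch, so no batch term was used and batch could not be separated from group. Where groups held at least 3 libraries, other splits of the same libraries were counted, except for the step from DN3 to DP in induced cells.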

Results

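RNA was measured in 76 libraries of 1000 sorted mouse cells each, which fall into 24 groups. Natural cells of 15 groups came from bone marrow and thymus: hematopoietic stem cells (HSC), multipotent progenitors (MPP), pro/pre-B cells, mature B, T and myeloid cells, bone marrow (BM) and thymic early T lineage progenitors (ETP), double negative thymocytes DN1 to DN4, double positive thymocytes (DP), and CD4 and CD8 single positive thymocytes (SP). Induced cells of the 9 stages from BM ETP to CD8 SP came from recipients of pro/pre-B cells transduced with Hoxb5, a homeobox transcription factor of stem cells. Groups held 2 to 4 libraries. Replicates 1 and 3 of the pro/pre-B group were identical in every gene, so they were counted once, which left 75 distinct libraries. The labels do not say whether libraries of a group came from different animals. The table gives no read counts. The smallest steps between low values placed the depth at 0.987 to 11.2 fragments per FPKM (fragments per kilobase of transcript, scaled to mapped fragments) and kilobase of transcript, with a median of 4.20. The myeloid libraries were the shallowest. Each library had 9828 to 12202 genes at 1 FPKM or more, and Pearson correlations across genes between libraries of a group were 0.939 to 0.985.

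The first question was where Hoxb5 RNA was present. Hoxb5 (ENSMUSG00000038700, GRCm38 chromosome 11, 96303336 to 96306121) was highest in natural HSC, at 4.50 ± 1.48 FPKM (SD, n = 4), and was 0.580 ± 0.250 FPKM (SD, n = 4) in MPP. The pro/pre-B libraries had 0.0216 ± 0.0374 FPKM (SD, n = 3). Among induced cells, thymic ETP had 2.74 ± 0.972 FPKM (SD, n = 3), CD4 SP 1.61 ± 0.513 (SD, n = 4) and DP 1.24 ± 0.646 (SD, n = 3), while every natural library of thymic ETP and CD4 SP was listed at 0. The difference passed the limma test in DP (log2 fold change 1.09, adjusted p = 4.48e-06), and also in thymic ETP (adjusted p = 3.34e-10), DN1 (adjusted p = 0.0327), CD4 SP (adjusted p = 2.82e-09) and CD8 SP (adjusted p = 0.0111), where the natural group was listed at 0. At DN1 the call was lost with quantile normalization (adjusted p = 0.315), with a replicate block (adjusted p = 0.0573), without natural DN1 libraries 1 and 2 and natural DN2 library 2, which was tried after seeing the data (adjusted p = 0.298), and without induced library 1, 2 or 4 or any 1 natural library (adjusted p from 0.0501 to 0.0876). With the 2 groups fitted alone it was lost in thymic ETP (adjusted p = 0.35) and DP (adjusted p = 0.101). It did not pass in BM ETP, DN2, DN3 or DN4, although DN2 passed with the 2 groups fitted alone (adjusted p = 0.0271) and DN3 with a pseudocount of 0.1 (adjusted p = 0.00891). In induced BM ETP the libraries had 0.358 ± 0.368 FPKM (SD, n = 2), against 0.313 ± 0.114 (SD, n = 3) in natural BM ETP. The FPKM values are low, and the deposited values do not separate transduced from endogenous transcripts.

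**Figure D1:**
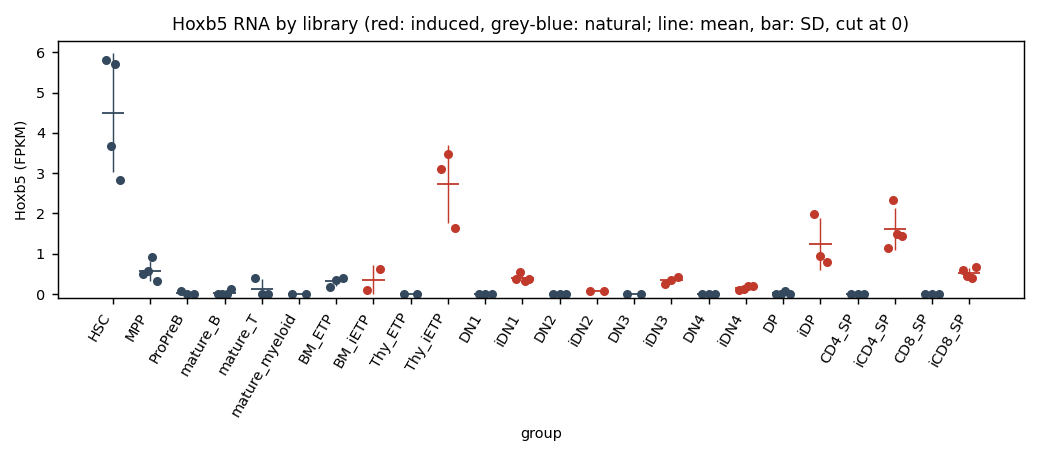
Hoxb5 RNA in FPKM (vertical axis) for each of the 75 distinct libraries by group (horizontal axis). Points are libraries, horizontal lines group means, vertical bars 1 SD, cut at 0. Natural HSC had the highest mean, 4.50 FPKM, and induced thymic ETP the highest among induced groups, 2.74 FPKM.

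Profiles of induced libraries were then placed among the natural groups by correlation across the genes tested, which are not independent replicates. All 3 induced DP, all 4 induced DN4, both induced DN2 and all 3 induced thymic ETP libraries correlated best with the natural group of their own stage, which made 12 of 29 induced libraries. For natural libraries, each left out of its own group's mean, the count was 44 of 46. A natural library can share sex and batch with its own group's mean, so this count is no equal standard for induced libraries. Noise in each group's mean also enters these ranks and was not tested. Retroposed copies of ribosomal protein genes were low in natural DN1 and CD8 SP libraries, and their reads can be shared with parent genes. This can lower the correlations of induced DN1 and CD8 SP libraries with their own stage, and its effect was not tested. Both induced BM ETP libraries correlated best with pro/pre-B cells (mean r = 0.919) and less with natural BM ETP (mean r = 0.853). All 4 induced CD4 SP and all 4 induced CD8 SP libraries correlated best with natural DN4 cells, the stage after beta selection of the T cell receptor. Of the induced DN1 libraries, 3 were nearest to DN4 and 1 to CD4 SP. Library 3 had r = 0.931 with DN4 and 0.9307 with CD4 SP, and library 4 had 0.924 and 0.9242, so these were near ties. All 3 induced DN3 libraries were nearest to natural DN2, as were both natural DN3 libraries.

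**Figure D2:**
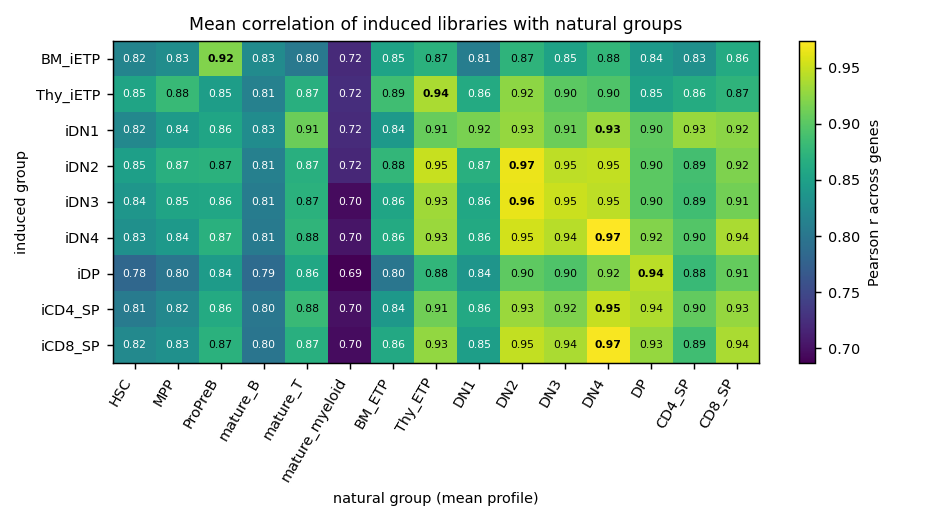
Mean Pearson correlation across genes of the libraries of each induced group (vertical) with the mean profile of each natural group (horizontal); bold marks the highest value of a line. Induced BM ETP was highest with pro/pre-B cells, and induced DN1, CD4 SP and CD8 SP with DN4.

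Induced BM ETP had more RNA of B lineage genes than natural BM ETP. Igll1 and Vpreb1, which form the surrogate light chain of the pre-B receptor, reached 3916 ± 488 FPKM (SD, n = 2) and 1712 ± 186 FPKM, against 2.71 ± 3.40 FPKM (SD, n = 3) and 1.59 ± 0.319 FPKM in natural BM ETP. Natural BM ETP instead held granule enzymes of neutrophil precursors. Mpo was 5666 ± 672 FPKM (SD, n = 3) there and 8.14 ± 4.77 FPKM (SD, n = 2) in induced cells, and Elane was 7038 ± 866 FPKM (SD, n = 3) there and listed at 0 in induced cells. The comparison asks how far the induced marrow progenitors matched the natural ones. In the B lineage list, 19 of 20 tested members rose, 1 fell and 0 did not pass (the same counts adjusted over the list alone, camera adjusted p = 1.61e-31). Vpreb3, which associates with the pre-B receptor, rose (log2 fold change 11.30 ± 0.52, SE), and so did Cd79a, a signaling chain of the B cell receptor (8.27 ± 0.31). In the stem and progenitor list, 2 of 20 tested members rose, 14 fell and 4 did not pass (3 and 15 adjusted over the list alone, camera adjusted p = 3.27e-12), with Cd34, a progenitor surface protein (-6.95 ± 0.32), and Flt3, a cytokine receptor (-4.70 ± 0.37), among those that fell. In the myeloid list, 0 of 20 tested members rose, 15 fell and 5 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 1.32e-20). The Hox genes other than Hoxb5 were lower: 0 of 11 tested members rose, 10 fell and 1 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 1.3e-07). The recombinase genes Rag1 (4.10 ± 0.35) and Rag2 (4.87 ± 0.46) rose within the beta selection list, where 8 of 12 tested members rose, 0 fell and 4 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 2.51e-08). In the T lineage list, 9 of 26 tested members rose, 4 fell and 13 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.0494, adjusted p = 0.117 with an estimated correlation). Its median log2 fold change was -0.02 and its mean 0.70, and its adjusted p was 0.208 with a pseudocount of 0.1 and 0.0521 with a replicate block. Il7r, the interleukin 7 receptor of lymphoid progenitors, rose (7.73 ± 0.29), while Cd27 fell (-6.18 ± 0.39). In the proliferation list, 14 of 20 tested members rose, 3 fell and 3 did not pass (14 and 4 adjusted over the list alone, camera adjusted p = 1.66e-05, adjusted p = 0.113 with an estimated correlation). For mitochondrially encoded genes, 11 of 13 tested members rose, 0 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 4.26e-08, adjusted p = 0.0819 with an estimated correlation), and mt-Co3 changed sign with quantile normalization (log2 fold change -0.39). In all, 5423 of 17416 genes differed, 2502 higher and 2921 lower in induced cells. Both induced libraries carried the same leading kappa and heavy chain variable segments, and the induced group held 2 libraries.

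Induced thymic ETP had less RNA of many dendritic and proliferation genes than natural thymic ETP. Cd74, the invariant chain of MHC class II, was 0.232 ± 0.212 FPKM (SD, n = 3) in induced and 455 ± 160.2 FPKM (SD, n = 2) in natural cells (log2 fold change -8.50 ± 0.59, SE). The class II chain H2-Ab1 fell (-7.05 ± 1.06), and H2-Eb1 was 334 ± 143 FPKM (SD, n = 2) in natural cells and listed at 0 in induced cells. Gal, the neuropeptide galanin, was 727 ± 78.6 FPKM (SD, n = 3) in induced cells and listed at 0 in natural cells. In the dendritic list, 0 of 12 tested members rose, 9 fell and 3 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 5.57e-23), with Irf8, a factor of dendritic and myeloid cells, among those that fell (-5.32 ± 0.55). In the proliferation list, 0 of 20 tested members rose, 16 fell and 4 did not pass (0 and 19 adjusted over the list alone, camera adjusted p = 1.25e-21). Plk1, a mitotic kinase, fell (-2.12 ± 0.62, its call was lost with a pseudocount of 0.1 and without induced library 1 or natural library 1 or 2, adjusted p from 0.104 to 0.157), as did Mki67, a marker of cycling cells (-1.77 ± 0.33). In the CD8 lineage and cytotoxic list, 1 of 18 tested members rose, 4 fell and 13 did not pass (1 and 6 adjusted over the list alone, camera adjusted p = 0.0016). Its granzymes parted, since Gzma fell (-5.95 ± 0.49) and Gzmb rose (2.88 ± 0.50, adjusted p = 0.0741 with a pseudocount of 0.1). In the beta selection list, 2 of 12 tested members rose, 4 fell and 6 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.00578). Cd3e, a T cell receptor signaling chain, fell (-2.06 ± 0.28), Dtx1, a Notch target, rose (1.88 ± 0.45, adjusted p = 0.147 without natural library 2), and Ptcra, the pre-T receptor alpha chain, was listed at 0 in induced cells against 17.7 ± 4.51 FPKM (SD, n = 2). In the Hox list, 0 of 11 tested members rose, 3 fell and 8 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.000696). For interferon genes, 2 of 16 tested members rose, 0 fell and 14 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.062 with an estimated correlation). In the single positive maturation list, 5 of 18 tested members rose, 1 fell and 12 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.0279, adjusted p = 0.167 with an estimated correlation), with an adjusted p of 0.063 with a replicate block, including the egress receptor S1pr1 (3.66 ± 0.48) and its regulator Klf2 (2.39 ± 0.51). A total of 1441 genes differed, 782 higher and 659 lower. Without natural library 1 the count was 882 and without natural library 2 it was 771, and 16 genes passed when the 2 groups were fitted alone. That fit lost the calls of Cd3e, Dtx1, Gzma, Gzmb, H2-Ab1, Irf8, Klf2, Mki67, Plk1 and S1pr1 (adjusted p from 0.128 to 0.371).

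Induced DN1 cells had less RNA of many natural killer, cytotoxic and dendritic genes than natural DN1 cells and more RNA of DP stage genes. Both groups had high means of the single positive maturation list in log2(FPKM + 1). The means were 7.074 to 7.186 in natural and 6.517 to 6.625 in induced DN1 libraries. Natural CD4 SP libraries had 7.496 to 7.793 and natural DN2 to DN4 libraries 3.301 to 4.7. In these genes both DN1 groups were thus nearer to CD4 SP than to later double negative cells. Gzmb, a granule protease of killer cells, was 0.831 ± 0.960 FPKM (SD, n = 4) in induced and 889 ± 22.9 FPKM (SD, n = 3) in natural cells (log2 fold change -9.09 ± 0.42, SE). Klrb1c, the killer cell receptor NK1.1, fell (-5.52 ± 0.45), as did Siglech, a receptor of plasmacytoid dendritic cells (-6.26 ± 0.61). Dntt, the enzyme that adds bases at receptor gene joins, rose (3.68 ± 0.15), as did Themis, a T cell signaling protein of positive selection (2.89 ± 0.19). In the CD8 lineage and cytotoxic list, 0 of 18 tested members rose, 12 fell and 6 did not pass (0 and 14 adjusted over the list alone, camera adjusted p = 1.29e-11). In the natural killer and innate list, 2 of 15 tested members rose, 10 fell and 3 did not pass (2 and 11 adjusted over the list alone, camera adjusted p = 5.28e-08). In the dendritic list, 1 of 12 tested members rose, 9 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 1.02e-09). In the DP stage list, 8 of 15 tested members rose, 0 fell and 7 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 1.99e-09). The single positive maturation list went the other way: 2 of 18 tested members rose, 5 fell and 11 did not pass (2 and 8 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.144 with an estimated correlation), and the adjusted p was 0.193 with a pseudocount of 0.1. For proliferation genes, 11 of 20 tested members rose, 0 fell and 9 did not pass (17 and 0 adjusted over the list alone, camera adjusted p = 1.06e-07). In the interferon list, 0 of 16 tested members rose, 8 fell and 8 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 0.000561). In the myeloid list, 0 of 20 tested members rose, 7 fell and 13 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 0.00057). The immunoglobulin constant list fell: 0 of 4 tested members rose, 3 fell and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.0507 with an estimated correlation). Igkc, the kappa light chain constant gene, ranged from 89.5 to 3446 FPKM among the 3 natural DN1 libraries. In the beta selection list, 4 of 12 tested members rose, 2 fell and 6 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.0745 with an estimated correlation), and its adjusted p was 0.052 with quantile normalization. Ctse, the protease cathepsin E, rose to 371 ± 11.2 FPKM (SD, n = 4) (log2 fold change 4.63 ± 0.57), and Malat1, a nuclear noncoding RNA, also rose (3.79 ± 0.44). Rps3a2, a retroposed copy of a ribosomal protein gene whose reads can be shared with its parent, was 0.942 ± 0.816 FPKM (SD, n = 3) in natural DN1 and 85.4 ± 6.07 FPKM (SD, n = 4) in induced DN1. In total 3280 genes differed, 1724 higher and 1556 lower. Without natural DN1 libraries 1 and 2 and natural DN2 library 2, which was tried after seeing the data, the count was 1505.

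At DN2 and DN3, fewer genes passed between induced and natural cells, and stress response genes were among the higher ones. Each of these comparisons held a group of 2 libraries. In the simulated data, 23% of 2-fold changes were found with the group sizes of DN3 and 53% with those of DP. Counts of stages with different group sizes are therefore not directly comparable. At DN2, Hspa1a, an inducible heat shock protein, was 24.4 ± 6.80 FPKM (SD, n = 2) in induced and 0.117 ± 0.104 FPKM (SD, n = 3) in natural cells (log2 fold change 4.48 ± 0.42, SE), and Ctse rose by 5.47 ± 0.68. Reads of Hspa1a and its neighbor Hspa1b can be shared, so the pair counts as 1 signal. Nr4a1, an early target of T cell receptor signaling, rose (1.98 ± 0.52, its call was lost with a pseudocount of 0.1, with a replicate block, and without induced library 1 or 2 or natural library 2 or 3, adjusted p from 0.0816 to 0.244). Cpa3, a mast cell protease, also rose (3.31 ± 0.65, its call was lost with a pseudocount of 0.1, with a replicate block and without natural library 3, adjusted p from 0.0542 to 0.147). The Notch target Dtx1 fell (-2.60 ± 0.45), as did Rag1 (-2.13 ± 0.35) and Lef1, a T lineage transcription factor (-2.06 ± 0.35). In the immediate early and stress list, 3 of 14 tested members rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 2.85e-06). In the T lineage list, 1 of 26 tested members rose, 3 fell and 22 did not pass (2 and 7 adjusted over the list alone, camera adjusted p = 2.82e-05). In the beta selection list, 0 of 12 tested members rose, 2 fell and 10 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.000237). For T cell receptor signaling genes, 2 of 11 tested members rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 2.82e-05). For mitochondrially encoded genes at DN2, 1 of 13 tested members rose, 0 fell and 12 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.000237, adjusted p = 0.244 with an estimated correlation). For stem and progenitor genes, 3 of 20 tested members rose, 0 fell and 17 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.000687, adjusted p = 0.111 with an estimated correlation), and the adjusted p was 0.0919 with a replicate block. In the DN2 comparison 262 genes differed, 153 higher and 109 lower, so 58.4% were higher, and 70.6% were higher when libraries were scaled to an equal total. The count was 133 without induced library 1 and 130 without induced library 2, it was 50 when the 2 groups were fitted alone, and it was 659 with library weights. The fit of these groups alone lost the calls of Cpa3, Ctse, Dtx1, Lef1, Nr4a1 and Rag1 (adjusted p from 0.325 to 0.621).

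At DN3, Hspa1a was 39.9 ± 9.06 FPKM (SD, n = 3) in induced and 0.208 ± 0.294 FPKM (SD, n = 2) in natural cells (log2 fold change 5.08 ± 0.42, SE). Atf3, a stress-induced transcription factor, was 10.6 ± 3.06 FPKM (SD, n = 3) in induced cells and listed at 0 in natural cells. Cd69, a surface marker of recent activation, rose (1.78 ± 0.41, adjusted p = 0.0942 without natural library 1), as did Malat1 (4.38 ± 0.52) and Ctse (3.86 ± 0.68). In the immediate early and stress list, 5 of 14 tested members rose, 0 fell and 9 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 7.11e-12). Among T cell receptor signaling genes, 2 of 11 tested members rose, 0 fell and 9 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.042, adjusted p = 0.459 with an estimated correlation), and the adjusted p was 0.069 with quantile normalization. Mitochondrially encoded genes gave a call as well: 2 of 13 tested members rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.000864, adjusted p = 0.654 with an estimated correlation). The DN3 comparison held 616 changed genes, 409 higher and 207 lower. The share that was higher was 66.4%, against 78% with libraries scaled to an equal total and 54.5% with quantile normalization. No gene passed limma's test when the 2 groups were fitted alone, where 1055 genes had an unadjusted p under 0.05, and the count was 394 without induced library 1, 315 without induced library 3, 365 with a replicate block and 210 with library weights. Fitting DN3 libraries alone ended the calls of Cd69, Ctse, Hspa1a and Malat1 (adjusted p from 0.237 to 0.674).

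At DN4, induced and natural cells differed in the fewest genes of the 9 stages, though not with library weights or with the groups fitted alone. Ctse was 167 ± 9.68 FPKM (SD, n = 4) in induced and 7.19 ± 3.98 FPKM (SD, n = 3) in natural cells (log2 fold change 4.50 ± 0.57, SE). Jun, an immediate early transcription factor, rose (1.66 ± 0.33, adjusted p = 0.115 without natural library 1), and so did Mid1, an X-linked ubiquitin ligase (3.88 ± 0.59), and Cpne8 (3.25 ± 0.30). Cd8b1, a chain of the CD8 coreceptor, fell (-1.94 ± 0.39, adjusted p = 0.14 with a pseudocount of 0.1), and so did Ccl5, a chemokine of cytotoxic cells (-2.10 ± 0.48, adjusted p from 0.14 to 0.152 without natural library 1 or 2), and Trib2, a pseudokinase (-2.45 ± 0.32). In the immediate early and stress list, 3 of 14 tested members rose, 0 fell and 11 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 2.69e-13). In the CD8 lineage and cytotoxic list, 0 of 18 tested members rose, 3 fell and 15 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.00264). The comparison gave 129 changed genes, 68 higher and 61 lower, and the higher share was 52.7% or, with libraries scaled to an equal total, 65.5%. The count was 77 without natural library 1, 374 with the 2 groups fitted alone and 1462 with library weights. The fit of DN4 groups alone lost the calls of Ccl5 and Jun (adjusted p from 0.0612 to 0.114).

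In DP cells, several T lineage genes were lower in induced cells. Lef1 was 16.1 ± 5.87 FPKM (SD, n = 3) in induced and 84.5 ± 12.4 FPKM (SD, n = 4) in natural DP cells (log2 fold change -2.38 ± 0.29, SE). Bcl11b, which fixes T cell identity, fell (-1.24 ± 0.19), as did Gata3, a T lineage regulator (-0.80 ± 0.20, adjusted p from 0.0521 to 0.0825 without induced library 3 or with library weights), and Hes1, a Notch target (-1.86 ± 0.41, adjusted p = 0.0613 with library weights). In the T lineage list, 0 of 26 tested members rose, 5 fell and 21 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.00316). This call was lost with quantile normalization (adjusted p = 0.153) and with libraries scaled to an equal total (adjusted p = 0.128). In the DP stage list, 2 of 15 tested members rose, 2 fell and 11 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.975). Ctse rose again (5.34 ± 0.57), as did Cdc42ep3, an effector of Cdc42 (4.18 ± 0.24), and Slc5a9, a sugar transporter (3.49 ± 0.43). Dusp6, a phosphatase that limits ERK signaling, fell (-4.25 ± 0.46), together with the mRNA export factor Alyref (-4.49 ± 0.59) and the splicing factor Srsf9 (-4.15 ± 0.48). Slc15a2, a peptide transporter, was 16.9 ± 1.76 FPKM (SD, n = 4) in natural and listed at 0 in induced DP cells. The DP comparison had 1804 changed genes, 841 higher and 963 lower. With libraries scaled to an equal total the higher share moved from 46.6% to 71.5%, 115 genes passed with the 2 groups fitted alone, and 737 passed with library weights. Named genes without a call in the fit of DP groups alone were Alyref, Bcl11b, Gata3, Hes1 and Slc5a9 (adjusted p from 0.0617 to 0.359).

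Induced CD4 SP cells had more RNA of Rag2, Dntt and proliferation genes than natural CD4 SP cells, and less RNA of maturation genes. Rag2 was 97.2 ± 18.8 FPKM (SD, n = 4) in induced and 0.0817 ± 0.0779 FPKM (SD, n = 3) in natural cells (log2 fold change 6.49 ± 0.39, SE). Dntt rose (5.64 ± 0.15). The mitotic activator Cdc20 rose (5.26 ± 0.44). S1pr1, the receptor used to leave the thymus, fell (-4.12 ± 0.40), and so did Ccr7, a chemokine receptor of mature thymocytes (-3.80 ± 0.45). In the single positive maturation list, 0 of 18 tested members rose, 17 fell and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 5.12e-20). In the proliferation list, 19 of 20 tested members rose, 0 fell and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 2.23e-22). In the DP stage list, 12 of 15 tested members rose, 0 fell and 3 did not pass (the same counts adjusted over the list alone, camera adjusted p = 1.28e-18). In the CD4 lineage list, 0 of 10 tested members rose, 9 fell and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 5.52e-10), with Zbtb7b, which directs CD4 commitment (-2.07 ± 0.31), and Foxp3, the regulatory T cell factor (-3.13 ± 0.22), among those that fell. In the CD8 lineage and cytotoxic list, 3 of 18 tested members rose, 12 fell and 3 did not pass (3 and 13 adjusted over the list alone, camera adjusted p = 2.8e-06). In the natural killer and innate list, 1 of 15 tested members rose, 10 fell and 4 did not pass (the same counts adjusted over the list alone, camera adjusted p = 5.18e-06). In the interferon list, 0 of 16 tested members rose, 8 fell and 8 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 5.18e-06). For T cell receptor signaling genes, 0 of 11 tested members rose, 6 fell and 5 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.00076). Mitochondrially encoded genes were lower: 0 of 13 tested members rose, 11 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 2.49e-10), although mt-Co1 changed sign with quantile normalization (log2 fold change 0.0648). For the T lineage list, 5 of 26 tested members rose, 13 fell and 8 did not pass (6 and 13 adjusted over the list alone, camera adjusted p = 0.0134), and its adjusted p was 0.105 with a pseudocount of 0.1 and 0.122 with libraries scaled to an equal total. Natural CD4 SP libraries also held S100a4, which fell in induced cells (-6.95 ± 0.83), and Gzmb at 68.4 ± 43.8 FPKM (SD, n = 3), which was listed at 0 in induced cells. A total of 4599 genes changed, 2436 higher and 2163 lower. The higher share was 53%, or 70.6% with libraries scaled to an equal total, and 2132 genes passed with the 2 groups fitted alone.

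Induced CD8 SP cells also had less RNA of maturation and cytotoxic genes. Natural CD8 SP libraries were themselves rich in proliferation RNA, with list means of 7.309 to 7.551 in log2(FPKM + 1). Natural DN4 libraries had 7.391 to 7.55 and natural CD4 SP libraries 5.007 to 5.367. The DP stage means were 6.079 to 6.21 in natural CD8 SP and 3.8 to 4.191 in natural CD4 SP libraries. Ccr7 was 3.52 ± 2.80 FPKM (SD, n = 4) in induced and 118 ± 36.3 FPKM (SD, n = 3) in natural cells (log2 fold change -4.85 ± 0.45, SE). Ccl5 fell (-7.25 ± 0.48), and so did Klrd1, an inhibitory receptor chain of killer cells (-5.82 ± 0.56), and Gimap4, a GTPase of lymphocytes (-4.59 ± 0.55). In the CD8 lineage and cytotoxic list, 0 of 18 tested members rose, 14 fell and 4 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 2.06e-23). In the single positive maturation list, 1 of 18 tested members rose, 15 fell and 2 did not pass (1 and 17 adjusted over the list alone, camera adjusted p = 2.15e-30). The natural killer and innate list gave a similar direction: 0 of 15 tested members rose, 8 fell and 7 did not pass (the same counts adjusted over the list alone, camera adjusted p = 2.78e-07). In the interferon list, 0 of 16 tested members rose, 7 fell and 9 did not pass (0 and 10 adjusted over the list alone, camera adjusted p = 8.91e-07). In the dendritic list, 0 of 12 tested members rose, 5 fell and 7 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 7e-08), with Cd74 (-4.40 ± 0.49) and H2-Aa (-4.57 ± 0.57) among those that fell. In the B lineage list, 0 of 20 tested members rose, 7 fell and 13 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 0.000512). Vpreb3 was 8.35 ± 1.10 FPKM (SD, n = 3) in natural cells (-3.09 ± 0.43). In the T lineage list, 0 of 26 tested members rose, 8 fell and 18 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 0.000397). For T cell receptor signaling genes, 0 of 11 tested members rose, 4 fell and 7 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 0.000309). For proliferation genes, 3 of 20 tested members rose, 0 fell and 17 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00142, adjusted p = 0.2 with an estimated correlation), and the adjusted p was 0.0812 with quantile normalization. In the DP stage list, 3 of 15 tested members rose, 0 fell and 12 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.0715 with an estimated correlation), and the call was also lost with a pseudocount of 0.1 (adjusted p = 0.0837), with quantile normalization (adjusted p = 0.189) and with libraries scaled to an equal total (adjusted p = 0.056). Ctse rose (4.69 ± 0.57). The retroposed copies Rps3a2 (0.271 ± 0.243 FPKM) and Rps27rt (7.27 ± 1.69 FPKM) were low in natural CD8 SP cells, as in natural DN1, and their reads can be shared with their parent genes. A total of 1852 genes changed, 980 higher and 872 lower. The higher share was 52.9%, or 40.4% with quantile normalization, and 2883 genes passed with library weights.

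Sex-linked RNA differed along with induced or natural origin at several stages. Xist, which silences 1 X chromosome in females, was between 4.21 and 16.3 FPKM in every induced DN1 to SP library. Ddx3y, a Y-linked gene, was 0 to 0.767 FPKM in those libraries. Natural DN1 to SP libraries had 3.71 to 32.5 FPKM of Ddx3y, except natural DN2 library 2 with 0.325 FPKM, and 0 to 1.78 FPKM of Xist, with 0.0850 FPKM in that library. In the BM ETP comparison Ddx3y was listed at 0 on both sides, while pro/pre-B cells had Ddx3y at 16.3 FPKM (SD 3.42, n = 3) and Xist listed at 0. Sex-linked RNA thus also differed between BM ETP of both sources and pro/pre-B cells. Induced thymic ETP held both Xist (4.28 ± 1.59 FPKM, SD, n = 3) and Ddx3y (3.29 ± 0.950 FPKM, SD, n = 3), and natural thymic ETP held Xist (7.34 ± 0.863 FPKM, SD, n = 2) with Ddx3y listed at 0.

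**Figure D3:**
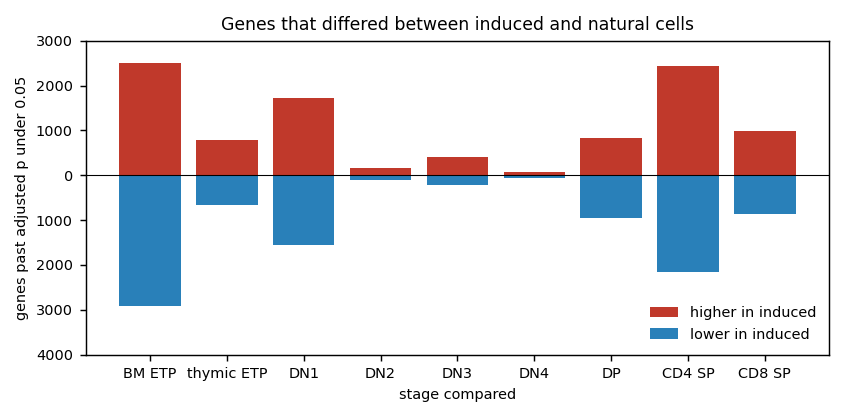
Genes past adjusted p under 0.05 in limma (vertical axis, number of genes) in the comparison of induced with natural cells at each stage (horizontal axis); red bars are genes higher in induced cells, blue bars, drawn downward, genes lower. BM ETP had the most genes (5423) and DN4 the fewest (129). Group sizes, and so the power to find changes, differed between stages.

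Averaged over the 9 stages, Ctse was the most raised gene that the naming rule gave (log2 fold change 4.21, SE 0.21, adjusted p = 2.78e-24), followed by Hspa1a (3.58 ± 0.13), Mid1 (3.04 ± 0.22) and Mmp11, a matrix protease (3.03 ± 0.32). Ccl5 (-2.74 ± 0.18), Cd74 (-2.49 ± 0.18) and Lgals3, a galectin (-3.29 ± 0.31), were lower. Over all stages, in the CD8 lineage and cytotoxic list, 0 of 18 tested members rose, 16 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 3.6e-14). In the myeloid list, 0 of 20 tested members rose, 14 fell and 6 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 2.61e-12). Its mean log2 fold change was -4.93 at BM ETP and -0.73 on average, and 5 members were higher and 2 lower at thymic ETP. In the B lineage list, 16 of 20 tested members rose, 3 fell and 1 did not pass (17 and 3 adjusted over the list alone, camera adjusted p = 1.37e-07). Its mean was 5.80 at BM ETP and 0.55 on average, while 7 members were lower at CD4 SP, with 2 higher, and 7 were lower at CD8 SP, with 0 higher. The average held 5203 changed genes, 2825 higher and 2378 lower, and the higher share moved from 54.3% to 70.1% with libraries scaled to an equal total. Genes higher at 7 or more stages numbered 15, genes lower at 7 or more numbered 8, and 0 passed in the same direction at all 9.

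**Figure D4:**
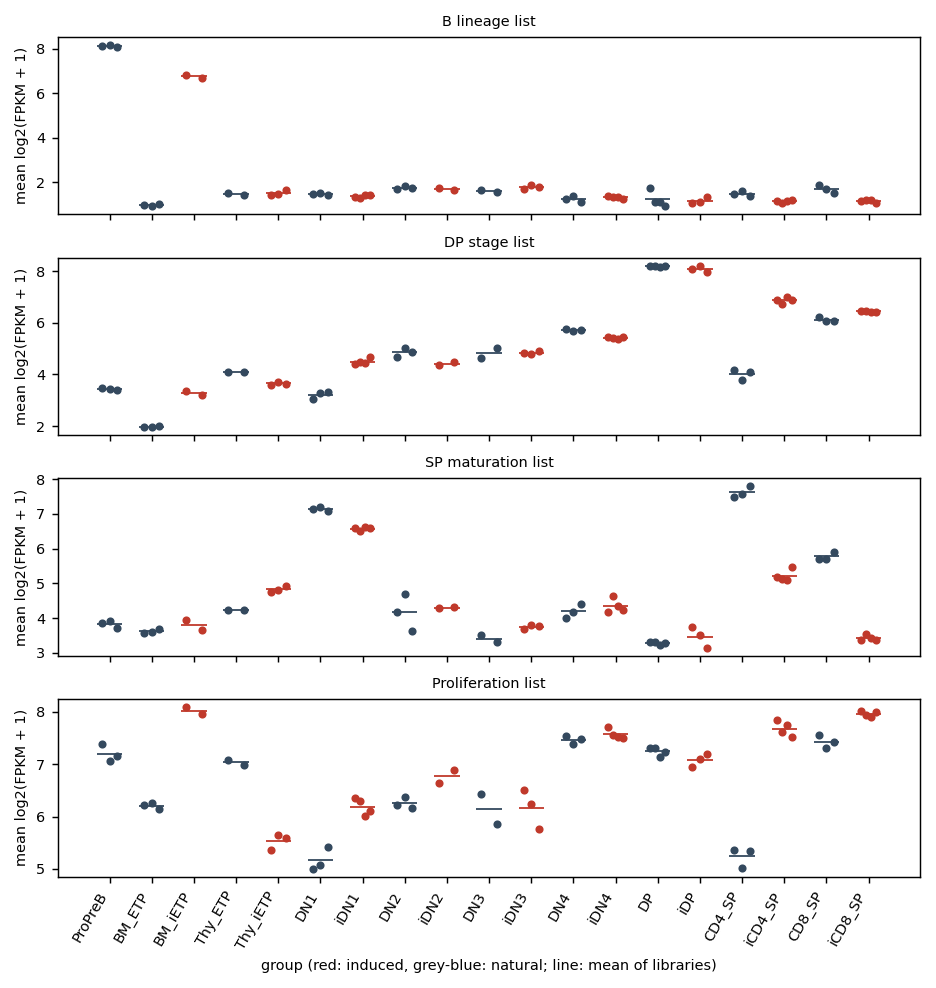
Mean log2(FPKM + 1) of the tested members of 4 gene lists (vertical axes) in each library of the pro/pre-B group and the 18 stage groups (horizontal axis); points are libraries and lines group means, red for induced and grey-blue for natural cells. B lineage genes were high in induced BM ETP and pro/pre-B libraries, and maturation genes were lower in induced than natural SP libraries.

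The next comparisons set the marrow progenitors and HSC against pro/pre-B cells, the cell type that was transduced. The pro/pre-B libraries had Ddx3y at 16.3 FPKM and Xist listed at 0. Induced BM ETP had Xist at 9.54 FPKM and Ddx3y listed at 0. Sex was thus not separated from the differences between them. Induced BM ETP held much B lineage RNA but had less RNA of several B lineage genes than pro/pre-B cells. Fcrla, a B cell Fc receptor-like protein, was 11.9 ± 6.55 FPKM (SD, n = 2) in induced BM ETP and 1036 ± 57.9 FPKM (SD, n = 3) in pro/pre-B cells (log2 fold change -6.42 ± 0.41, SE). Ms4a1, which encodes CD20, fell (-5.43 ± 0.35), and Iglc2, a lambda light chain constant gene, was 733 ± 233 FPKM (SD, n = 3) in pro/pre-B cells and listed at 0 in induced BM ETP. Bmi1, a Polycomb gene of stem cell renewal, was 1382 ± 80.6 FPKM (SD, n = 2) against 10.4 ± 2.17 FPKM (SD, n = 3) (6.94 ± 0.41). Ctse (6.72 ± 0.68) and Atf3 (5.47 ± 0.68) also rose. Both induced libraries had the same leading kappa and heavy chain variable segments, so they may not be independent samples. The source of these rises was not tested. In the B lineage list, 1 of 20 tested members rose, 11 fell and 8 did not pass (2 and 12 adjusted over the list alone, camera adjusted p = 1.06e-07). Vpreb2, the other form of the Vpreb1 chain with which it can share reads, was its riser (3.05 ± 0.27). In the erythroid list, 6 of 9 tested members rose, 0 fell and 3 did not pass (the same counts adjusted over the list alone, camera adjusted p = 3.89e-07), led by the alpha globin gene Hba-a2 (5.34 ± 0.50), whose reads can be shared with Hba-a1. In the immediate early and stress list, 8 of 14 tested members rose, 1 fell and 5 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.000114). In the immunoglobulin constant list, 0 of 4 tested members rose, 2 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.00272). For proliferation genes, 5 of 20 tested members rose, 0 fell and 15 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 0.00201, adjusted p = 0.291 with an estimated correlation). In the myeloid list, 5 of 20 tested members rose, 0 fell and 15 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 0.00882, adjusted p = 0.169 with an estimated correlation). This comparison had 2698 changed genes, 1410 higher and 1288 lower. The count was 1706 without induced library 2, and 13 with the 2 groups fitted alone. That fit had no call for Atf3, Ctse, Fcrla, Hba-a2, Ms4a1 and Vpreb2 (adjusted p from 0.0573 to 0.273).

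Natural BM ETP and HSC differed more from pro/pre-B cells. In natural BM ETP, Prtn3, a neutrophil granule protease, was 7513 ± 676 FPKM (SD, n = 3) against 0.418 ± 0.724 FPKM (SD, n = 3) (log2 fold change 12.48 ± 0.37, SE), and Lmo2, a stem and progenitor regulator, rose (4.40 ± 0.37). Cd79a (-9.69 ± 0.28) and Igll1 (-9.71 ± 0.45) fell. In the B lineage list of that comparison, 0 of 20 tested members rose, 20 fell and 0 did not pass (the same counts adjusted over the list alone, camera adjusted p = 1.03e-47). In its myeloid list, 18 of 20 tested members rose, 0 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 7.78e-25). In its stem and progenitor list, 16 of 20 tested members rose, 2 fell and 2 did not pass (the same counts adjusted over the list alone, camera adjusted p = 4.13e-14). A total of 5768 genes changed, 3174 higher and 2594 lower. In HSC, Hlf, a stem cell transcription factor, rose (5.98 ± 0.24), as did Ifitm1, an interferon-induced membrane protein (10.01 ± 0.60). Ighm, the IgM heavy chain gene, fell in HSC (-11.94 ± 0.29). In the stem and progenitor list, 17 of 20 tested members rose, 0 fell and 3 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 8.25e-18). In the Hox list, 11 of 11 tested members rose, 0 fell and 0 did not pass (the same counts adjusted over the list alone, camera adjusted p = 1.41e-10). In the proliferation list, 0 of 20 tested members rose, 20 fell and 0 did not pass (the same counts adjusted over the list alone, camera adjusted p = 1.4e-13). Hoxb5 itself was higher in HSC (log2 fold change 2.39, SE 0.17, adjusted p = 1.7e-18). This comparison had 7182 changed genes, 4263 higher and 2919 lower, and the median of all genes moved to 0.11 with a pseudocount of 0.1 and 0.14 with libraries scaled to an equal total.

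From DN3 to DP, thymocytes gain both coreceptors and lose early signaling genes, and both cell sources showed this. Cd8a rose by 9.39 ± 0.37 (log2 fold change ± SE) in natural and 9.54 ± 0.35 in induced cells. Cd4 rose by 6.09 ± 0.25 in natural cells, and in induced cells it was listed at 0 at DN3 and was 152 ± 13.8 FPKM (SD, n = 3) at DP. Il2ra, the CD25 receptor of DN2 and DN3 cells, fell in natural (-7.40 ± 0.30) and induced cells (-6.76 ± 0.28). The gamma receptor constant gene Tcrg-C2 fell in both as well (-8.52 ± 0.54 and -8.35 ± 0.50). In natural cells, in the DP stage list, 11 of 15 tested members rose, 0 fell and 4 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 3.6e-20). Induced cells gave, for the same list, 11 of 15 tested members rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone, camera adjusted p = 4.09e-25). In the beta selection list, natural cells gave 2 of 12 tested members rose, 7 fell and 3 did not pass (the same counts adjusted over the list alone, camera adjusted p = 3.75e-05). Induced cells gave 3 of 12 tested members rose, 8 fell and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 3.59e-06). Natural cells had 4300 changed genes, 2132 higher and 2168 lower, and induced cells 3307, 1422 higher and 1885 lower. Both sources shared 893 genes that rose, against 174 if independent, and 1105 that fell, against 235 if independent. Fold changes correlated with r = 0.623 across genes. The numbers for independence were taken over all 17416 tested genes. These include genes expressed in neither stage, so the numbers are lower than they would be among expressed genes. With libraries scaled to an equal total, the higher share in induced cells moved from 43% to 57.4%. With the 2 groups fitted alone the counts were 793 and 1390, and with library weights natural cells gave 2454.

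The test of the difference between both steps passed for 493 genes, 167 higher and 326 lower in the induced step. Immediate early and stress genes were among them: in that list, 0 of 14 tested members rose, 7 fell and 7 did not pass (1 and 9 adjusted over the list alone, camera adjusted p = 4.09e-12). Fos (-2.30 ± 0.44) and Junb (-2.71 ± 0.52), parts of the AP-1 factor, were lower in the induced step than in the natural one, as were Cd69 (-4.18 ± 0.53) and Malat1 (-4.64 ± 0.68). The higher share was 33.9%, and 45.3% with libraries scaled to an equal total or 48.1% with quantile normalization. The count was 104 with the 4 groups fitted alone and 150 with library weights. In the fit of these groups alone there was no call for Fos and Junb (adjusted p from 0.0548 to 0.157).

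The last comparison asked whether induced CD4 SP and CD8 SP cells diverged as natural ones did. In natural cells, Cd40lg, the helper ligand CD154, rose in CD4 SP over CD8 SP cells (5.40 ± 0.38, log2 fold change ± SE), and so did Zbtb7b (4.32 ± 0.33) and Tnfrsf4 (5.02 ± 0.65). Cd8a fell in natural (-7.55 ± 0.35) and induced cells (-4.17 ± 0.30), and Cd4 rose in natural (4.76 ± 0.24) and induced cells (3.77 ± 0.21). Induced CD4 SP cells also rose in Cd40lg (2.80 ± 0.33) and in Ccr7 (3.41 ± 0.41). In the CD4 lineage list, natural cells gave 9 of 10 tested members rose, 0 fell and 1 did not pass (the same counts adjusted over the list alone, camera adjusted p = 6.61e-15). Induced cells gave 6 of 10 tested members rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone, camera adjusted p = 7.62e-12). For single positive maturation genes, natural cells gave 16 of 18 tested members rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 4.04e-13). Induced cells gave 13 of 18 tested members rose, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone, camera adjusted p = 1.47e-28). In the proliferation list of natural cells, 0 of 20 tested members rose, 20 fell and 0 did not pass (the same counts adjusted over the list alone, camera adjusted p = 2.22e-23). In that of induced cells, 0 of 20 tested members rose, 4 fell and 16 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.175 with an estimated correlation), and the adjusted p was 0.0542 with quantile normalization. Natural cells had 3948 changed genes, 2162 higher and 1786 lower, and induced cells 1312, 813 higher and 499 lower. Retroposed copies of ribosomal protein genes were low in natural CD8 SP but not natural CD4 SP libraries. Their reads can be shared with parent genes, and they can add to the natural count and to the difference between sources below. Both sources shared 502 genes higher in CD4 SP, against 101 if independent, and 236 lower, against 51.2 if independent. Fold changes correlated with r = 0.315 across genes. As for the step from DN3 to DP, the numbers for independence include genes expressed in neither stage and are thus low. The higher share moved from 54.8% to 40.2% in natural and from 62% to 80.2% in induced cells with libraries scaled to an equal total. The natural count was 1360 with the 2 groups fitted alone, and the induced count 2407 with library weights.

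The CD4 against CD8 difference itself differed between sources for 1404 genes, 740 higher and 664 lower in induced cells. Rag2 (5.98 ± 0.54), Dntt (4.50 ± 0.21) and the mitotic gene Cdc20 (4.63 ± 0.62) were lower in CD4 SP than CD8 SP among natural cells and less so, or higher, among induced cells. Foxp3 was in the other direction (-2.88 ± 0.31). In the DP stage list, 9 of 15 tested members rose, 1 fell and 5 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 9.46e-20). For proliferation genes, 16 of 20 tested members rose, 0 fell and 4 did not pass (18 and 0 adjusted over the list alone, camera adjusted p = 9.46e-20). In the CD4 lineage list, 0 of 10 tested members rose, 6 fell and 4 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 2.19e-07). The CD8 lineage and cytotoxic list gave 5 of 18 tested members rose, 3 fell and 10 did not pass (the same counts adjusted over the list alone, camera adjusted p = 0.00536), and its adjusted p was 0.0797 with a pseudocount of 0.1. The higher share was 52.7%, or 77.6% with libraries scaled to an equal total, which moved the median of all genes to 0.13. The p53 response list and the thymic stroma list passed in 0 of 19 comparisons, with lowest adjusted p of 0.2 and 0.268.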

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

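Chosen only after the result was seen were the tests of depth, of random loss, of a constant share of pro/pre-B cells, of sex and of the Hoxb5 level, and all splits of libraries except those of natural BM ETP against pro/pre-B cells, and the tests of random loss, of a constant share, of sex and of the Hoxb5 level replaced earlier versions whose outcomes were known.

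In 3 of 25 sets of values from groups of 4 libraries, 1 library stood apart from the others, and chance does this in about 1 in 20 groups. Ctse was 387.9 FPKM in induced DN1 library 1 and 364.6 to 366.6 in the others. Hoxb5 was 0.0891 FPKM in natural DP library 3 and 0.116 FPKM in mature B library 4, and 0 in the other libraries of those groups, where any value above 0 stands apart, so that rate holds for neither.

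The step from DN3 to DP differed between sources for 493 genes, by a test of the difference itself. The log2 differences were -4.18 for Cd69, -2.30 for Fos, -2.71 for Junb and -4.65 for Malat1. The natural DN3 group held 2 libraries.

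The difference of CD4 SP and CD8 SP differed between sources for 1404 genes, by the same kind of test, with log2 differences of 5.98 for Rag2, 4.63 for Cdc20, 4.50 for Dntt and -2.88 for Foxp3. When induced and natural libraries were regrouped within each stage, 5 of 100 draws gave as many genes, the real one included, and the highest other gave 2698, so chance was not excluded for this count. Of the draws that gave as many, 2 kept the real groups of 1 stage, and so its difference between sources, and 2 did not.

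Splits of the libraries gave as many genes in 1 of 35, the real one, in 7 comparisons. That is the lowest share that 35 splits can give, and these splits were chosen after the counts were seen. The real groups led each time, which speaks against chance but does not exclude it. The real counts and highest others were 3280 and 1828 at DN1, 129 and 32 at DN4, 1804 and 1357 at DP, 4599 and 2914 at CD4 SP, and 1852 and 850 at CD8 SP. They were 7182 and 5268 for HSC against pro/pre-B cells, and 1312 and 84 for induced CD4 SP against CD8 SP. The 10 splits of natural BM ETP against pro/pre-B cells (5768, highest other 117) and of natural CD4 SP against CD8 SP (3948, highest other 184) are too few for a share under 0.05.

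Retroposed copies of ribosomal protein genes were near 0 in natural DN1 and CD8 SP libraries: Rps3a2 was at most 1.42 FPKM there and at least 57.1 FPKM in the other natural DN2 to CD4 SP libraries. Over 78 ribosomal protein pseudogenes not used to find the pattern, the median log2 difference was -1.36 (quartiles -4.09 and -0.10), 42 were lower by more than 1, and 81 ribosomal protein genes had a median of -0.10. Lower depth was excluded, since these 6 libraries had a median of 3.84 fragments per FPKM and kilobase against 3.69 in the others. A candidate explanation is that reads matching several copies were handled differently in these libraries, and a test that could have gone the other way met it. The labels name no such batch, and no biological explanation was tested.

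Both induced BM ETP libraries were led by the kappa segment Igkv2-137, with 68.3% and 84.9% of kappa variable FPKM, while the leading segment of pro/pre-B libraries held at most 13.8%. A constant share of mixed pro/pre-B cells was argued against by 24 abundant pro/pre-B genes other than immunoglobulin segments and small RNAs, of which 12.5% (3: Fcmr, Fcrla and Ms4a1) lay below 0.1 of the median ratio in both libraries, with Fcrla at 1.60% and 0.703% of its pro/pre-B level against medians of 44.3% and 50.5%. A subset of pro/pre-B cells was not tested. Random loss of molecules was not decided by its test: the heavy chain segment Ighv4-1 led both libraries with 79.4% and 100%, but with heavy chain variable totals of only 30.4 and 10.8 FPKM. Loss acting separately in each library would not favor the same segment in both. Igkv2-137 was 147.3 FPKM in pro/pre-B cells and 1249 and 1435 FPKM here. Iglc2 and Igkv11-106, at 733.3 and 267.9 FPKM in pro/pre-B cells, were listed at 0 in both. These values argue against loss as the only source. Some loss stays open, since Igkv3-7 was 84.81 and 0 FPKM and lambda leaders differed. Outgrowth of 1 or a few B lineage clones may be the source, but its test on kappa joining segments was void, since the leading share was 0 with all of them listed at 0, and shared input cells or RNA were not tested.

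Higher in induced cells at 7 or more stages were 15 genes, among them Ctse, Mid1, Hspa1a and Xist. With overlapping genes and Hspa1a and Hspa1b counted once, they made 12 loci, and sex of the animals stays open, since 5 of the 12 were also higher in the BM ETP comparison, where Ddx3y was listed at 0 on both sides, and that comparison was among those used to choose them. The level of Hoxb5 RNA at sorting stays open as well: 3 of 12 loci were higher at thymic ETP, which had the most Hoxb5 among induced groups, against 5 to 12 in the other comparisons, and the choice of genes sets part of that range. A strain or donor variant could place the genes near each other. Within the distance set beforehand lay 2 pairs, more than the 95th percentile of 1 in random sets (share 0.0214). Both pairs overlap on the chromosome and can share reads, so the result was not counted. Of the same genes, Cxcr4, Ctse and Csrp1 lie on chromosome 1, with starts at 128588199, 131638306 and 135720061. They are farther apart than that distance, so the test could not count them, and a wider interval was not tested. A strain or donor variant thus stays open and cannot be told apart from the other explanations. Irradiation, age and transplantation of the recipients were not tested and stay open.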

How the results depend on the processing

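The fits without the myeloid group, with protein-coding genes alone and without natural DN1 libraries 1 and 2 and natural DN2 library 2 were chosen after the data were seen. Of 366 alternative values of the counts, 337 were within 1.5 times of the count reported and 29 were not. Over all genes that the naming rule admits for the lists described, 27872 of 29248 alternative values stayed on the same side of the threshold with no sign change of a called value, 1080 lost the call, 294 gained one and 2 changed sign. Both sign changes were with quantile normalization: mt-Co3 in the BM ETP comparison (-0.39) and mt-Co1 in the CD4 SP comparison (0.0648), and the cause was not tested. Of the 116 gene examples in the report, 35 lost the call when only the groups compared were fitted and 11 lost it under another alternative. For described lists, 494 of 528 values were unchanged in call and 34 lost it. The count of induced libraries nearest to their own stage was 12 of 29 under every alternative tried. None of these alternatives was set to leave out the retroposed copies that were low in natural DN1 and CD8 SP libraries.

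With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the counts were 16 at thymic ETP, 50 at DN2, 0 at DN3 (limma, 1055 at an unadjusted p under 0.05), 374 at DN4, 115 at DP and 2132 at CD4 SP. They were 13 for induced BM ETP against pro/pre-B cells, 793 for natural and 1390 for induced DN3 to DP, 104 for the difference of these steps, and 1360 for natural CD4 SP against CD8 SP. With library weights they were 659 at DN2, 210 at DN3, 1462 at DN4, 737 at DP, 2883 at CD8 SP, 2454 for natural DN3 to DP, 150 for the difference of the DN3 to DP steps and 2407 for induced CD4 SP against CD8 SP. DN3 gave 365 with a replicate block. DN1 gave 1505 without natural DN1 libraries 1 and 2 and natural DN2 library 2. The cause of these moves was not tested for any of these settings, and the DN4 count rose with fewer libraries in the fit.

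Leaving out each library in turn gave 4099 to 4957 genes at BM ETP, 771 to 1398 at thymic ETP, 2598 to 2995 at DN1, 130 to 330 at DN2, 315 to 576 at DN3, 77 to 108 at DN4, 1339 to 1865 at DP, 3821 to 4363 at CD4 SP and 1305 to 1580 at CD8 SP. The average gave 4858 to 5252. Against pro/pre-B cells the ranges were 1706 to 2552 for induced BM ETP, 4985 to 5358 for natural BM ETP and 6452 to 6810 for HSC. From DN3 to DP they were 3110 to 4238 in natural and 2675 to 2914 in induced cells, and 349 to 637 for the difference. For CD4 SP against CD8 SP they were 3279 to 3714, 1025 to 1226 and 1141 to 1550. The libraries that moved a count by over 1.5 times were natural thymic ETP 1 (882) and 2 (771), induced DN2 1 (133) and 2 (130), induced DN3 1 (394) and 3 (315), natural DN4 1 (77) and induced BM ETP 2 (1706). A library left alone in its group was assumed to vary like the other groups. Depth limits what can be said of genes at low FPKM, Hoxb5 among them.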

Other observations

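The tests of receptor segments below were all chosen only after the result was seen.

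T cell receptor beta variable segments were spread over many genes in induced thymocytes. In 24 induced DN1 to SP libraries, the leading Trbv segment held 11.2% to 21.2% of Trbv FPKM (median 14.1%), and 13 to 19 of 20 segments had at least 1 FPKM. In 21 natural DN1 to SP libraries the leading share was 10.8% to 47.2% (median 15.8%), where 47.2% was natural DN2 library 2 and the next highest 33.2%, and in 3 mature T libraries 12.5% to 17.6%. The difference between sources was not tested.

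Igkv16-104 led the kappa variable segments of all 3 natural DN1 libraries, with 903 FPKM (100% of kappa variable FPKM), 115 FPKM (98.5%) and 1.71 FPKM (100%). Gal was 727 ± 78.6 FPKM (SD, n = 3) in induced thymic ETP.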
